A study of Homo sapiens with 4 samples.

How the data were processed

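The data are 4 Affymetrix arrays of total RNA from U87TR-Da cells, 1 each for silenced and induced DACH1 in medium labelled serum and serum-free. Labelled cRNA was made from 6 µg of total RNA, per the labels' protocols. The deposited values are a signal intensity per probe set on a linear scale, made with MAS5 per the submitters' processing notes. The version of MAS5, its target intensity and the chip definition are not given in the sources used here. The values themselves show 1 scaling factor per array: the means after trimming 2% of the probe sets at each end lie between 99.60 and 99.62. MAS5 subtracts an estimate of background from mismatch probes, so low signals are noisy on the log scale, and no detection calls were used here. Each sample had 1 column, 0 columns were left unused, and no 2 columns were alike (at most 569 of 54613 probe sets had equal signals).

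Probe sets were named from the platform annotation in GEO, with symbols updated through Entrez identifiers for 99.9% of those with 1 gene. Of 54613 probe sets, 41091 had 1 gene, 1801 several, and 11721 were not listed and stay unnamed here. A gene was represented by its probe set with the highest mean log2 signal over the 4 arrays, which gave 19775 genes. Signals under the 40th percentile of all signals (10.9) were set to it before log2. A gene entered a comparison of 2 arrays if at least 1 of them reached the median of all signals (17.2), and entered the limma fit if 2 of the 4 did. A fold against a signal at the floor is written "at least", and no fold is given where both arrays lie at the floor.

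With 1 array per condition, a difference between 2 arrays has no test, and genes were counted at 2-fold. The only fit with a residual degree of freedom was limma (lmFit and eBayes) on log2 signals with DACH1 state and medium as terms and no interaction, adjusted by Benjamini-Hochberg. Its error is the interaction of both factors in single arrays, and nothing in the labels says that cultures were repeated, so its p-values measure only the spread between these arrays. The fit was tested on simulated data over 12103 genes, with 200 changed between DACH1 states by the same amount in both media. Through the adjustment, recovery depends on how many genes change, so the shares found need not hold for the real arrays. It recovered 0 of 55 genes changed 2-fold, 68% of 75 changed 4-fold and 91.4% of 70 changed 8-fold, with 14 calls among 11903 unchanged genes.

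The design, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. There were 25 lists holding 452 different genes, of which 31 were not named here. The median log2 difference of a list was set beside 10000 random lists matched on mean signal in 20 bins. The named genes were DACH1 and FGF2, up to 10 genes per direction with the largest smaller difference among those 2-fold different in both pairs, the 5 highest and 5 lowest measured genes and 3 bounds per direction of each pair, the 5 highest and 5 lowest differences of differences, and up to 4 members of each list per factor. The text gives a part of them, and genes outside the rule are said to be so.

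The alternatives were quantile normalization, no floor, a pseudocount equal to the floor, no filter, every array above the median, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, a variance prior with a trend, and each array left out. A floor of 50 with at least 1 array at 100 or more, or 2 in the limma fit, was added after seeing the data. The planned ratio of control probe sets for RNA quality was not analysed here, since the table holds 0 such probe sets. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.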

Results

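Gene expression was measured in U87TR-Da, a derivative of the human glioblastoma line U87MG in which doxycycline can switch on DACH1, a nuclear repressor of transcription of the Dachshund family. Total RNA from 4 cultures was hybridised to 4 oligonucleotide arrays, 1 per condition. The cells were DACH1-silenced or DACH1-induced, and each state was grown either in DMEM with 10% fetal bovine serum or in a serum-free Neurobasal medium with N-2, B-27, basic FGF and EGF. The labels of all 4 samples, the silenced ones included, carry the same protocol line of 1 µg/mL doxycycline for 72 h, so the labels do not say how the silenced cells were handled. Each array reported 54613 probe sets. The median signal was 16.5 on the silenced and 15.7 on the induced array labelled serum, and 19.3 and 17.1 on those labelled serum-free. No condition was replicated, and the number of arrays limits the precision of every value. The media are called "labelled serum" and "labelled serum-free" throughout, for a reason given with the comparison of the media.

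DACH1 was read first, because it checks the labels. The brightest of the 3 probe sets for DACH1 gave 126.0 on the silenced and 4431 on the induced array labelled serum, a 35.2-fold higher signal. On the arrays labelled serum-free it gave 32.5 and 875.1, which was 26.9-fold higher. The induced level itself was 5.06-fold lower in the array labelled serum-free. The other 2 probe sets were low on every array: 1 read between 0.4 and 8.3, and 1 between 2.9 and 24.7. With the latter alone the log2 difference was 0.10 and -0.15 in the 2 media. Where these probe sets lie on the transcript was not analysed here.

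The first question of the study was what DACH1 induction does in U87TR-Da cells in serum. In the arrays labelled serum, several genes of the NF-kB and cytokine list were far lower with DACH1 induced. Interleukin gene IL6 went from 5184 in the silenced to 124.5 in the induced culture, which was 41.6-fold lower, and PTGS2, the inducible prostaglandin synthase, was 33.5-fold lower (3155 and 94.3). FGF2, which encodes basic FGF, was 7.05-fold lower (1476 and 209.3), with 6.51-fold for its other probe set, and RSPO3, a secreted enhancer of Wnt signalling, was 27-fold lower, from a signal of 945. PDGFRA, the platelet-derived growth factor receptor alpha gene, was 33.3-fold higher (19.7 and 656.2).

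Of 12190 genes compared in this pair, 355 were at least 2-fold higher and 581 at least 2-fold lower with DACH1 induced, 7.7% of the genes. Among these, 363 had no array at or above a signal of 50. None of these single-pair differences has a replicate check, so "higher" and "lower" describe these 2 arrays. Other genes with the largest measured differences were GALNT5, a glycosyltransferase gene, 21.7-fold lower, and the integrin gene ITGB8, 22.3-fold lower. CH25H, which encodes cholesterol 25-hydroxylase, was at least 23.3-fold lower, since its induced signal lay under the floor of 10.9. DPYD, at least 8.85-fold lower, and CYP19A1, at least 7.23-fold lower, were bounds of the same kind. Higher with DACH1 were the imprinted gene MEST (9.51-fold), the heme oxygenase gene HMOX1 (8.21-fold, from 182.4 to 1498) and CALB2 (7.91-fold).

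The list of NF-kB and cytokine genes had 12 of 21 measured members at least 2-fold lower and 0 higher, with a median log2 difference of -1.17. Its median lay under all of the 10000 random lists of the same size and signal, a description of these arrays only. CXCL1 was 15.8-fold lower, CXCL3 10.0-fold, CXCL2 3.72-fold and CCL20 3.39-fold, while IL1B was at 7569 and 7795. Not all cytokine genes shared this: IL24 read 1779 and 1692, IL1RN was 1.87-fold higher and IL33 4.80-fold higher. ATF4 targets of the amino acid response had 8 of 27 members lower and 0 higher, with a median of -0.52. Among them GDF15 was 3.54-fold lower, SLC7A11 3.02-fold, STC2 2.71-fold and the asparagine synthetase gene ASNS 2.17-fold. The 16 genes of ER chaperones and the unfolded protein response had a median of -0.43, with none past 2-fold.

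Several lists lay above their random lists. All 24 genes of G2 and M phase were above 0 in this pair, with a median of 0.37, and 17 of 21 genes of S phase, with a median of 0.42, but none of either list reached 2-fold. Cholesterol biosynthesis had a median of 0.58, with 16 of 18 genes above 0: HMGCS1, which encodes an HMG-CoA synthase, was 3.14-fold higher and SQLE 2.27-fold. The TGF-beta and BMP response had a median of 0.55, with BMP2 4.03-fold, INHBA 3.68-fold and ID1 3.66-fold higher and TGFB2 lower at 316.7 and 93.2. The list of hypoxia and glycolysis (median 0.31) had 13 of 20 members above 0 and 7 below. In it NDRG1 was 3.74-fold and the glucose transporter gene SLC2A3 2.27-fold higher, while ADM was 1.91-fold lower. Neural stem and progenitor markers had a median of 0.39 but were mixed, with 7 of 12 above 0 and 5 below, and SOX4 4.71-fold higher. The serum response list had a median of 0.25 but a mean of -0.05.

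Neuronal markers were mixed, with a median of -0.83 over 7 genes, 3 of them at least 2-fold lower and 2 above 0. MAP2 was at least 4.04-fold and SNAP25 2.34-fold lower, while the brightest, TUBB3, was 1.76-fold higher (1279 and 2249) and GAP43 at least 1.64-fold higher. With a floor of 50 and only genes with an array at 100 or more, which leaves out MAP2 and GAP43, that list median came to -0.18. SLC1A3, an astrocyte glutamate transporter gene, read 135 in the silenced and 12.8 in the induced culture, although the 7 astrocyte markers had a median of -0.06. The Wnt antagonist gene DKK1 was 14.5-fold lower, in a Wnt list with a median of 0.11 and a mean of -0.14. The FGF and ERK list had a median of 0.14 and a mean of -0.14: besides FGF2, ETV1 was 3.74-fold and the ERK phosphatase gene DUSP6 2.35-fold lower, while SPRY2 was 1.91-fold higher. Genes tied to DACH1 in earlier work had a median of -0.26, with FGF2, CXCL8 and IL6 the 3 of 10 that were at least 2-fold lower. The FGF and ERK, Wnt and astrocyte lists and the genes tied to DACH1 lay within the range of 95% of random lists. So did the EYA and PAX network (-0.18), oligodendrocyte markers (0.52), matrix genes (0.06, with a mean of -0.16, and -0.01 with quantile normalization), fatty acid synthesis (0.19), p53 response (-0.06), respiratory chain (0.07), interferon response (-0.25), Notch pathway (-0.11), markers of other cell types (0.21) and housekeeping genes (0.06).

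**Figure D1:**
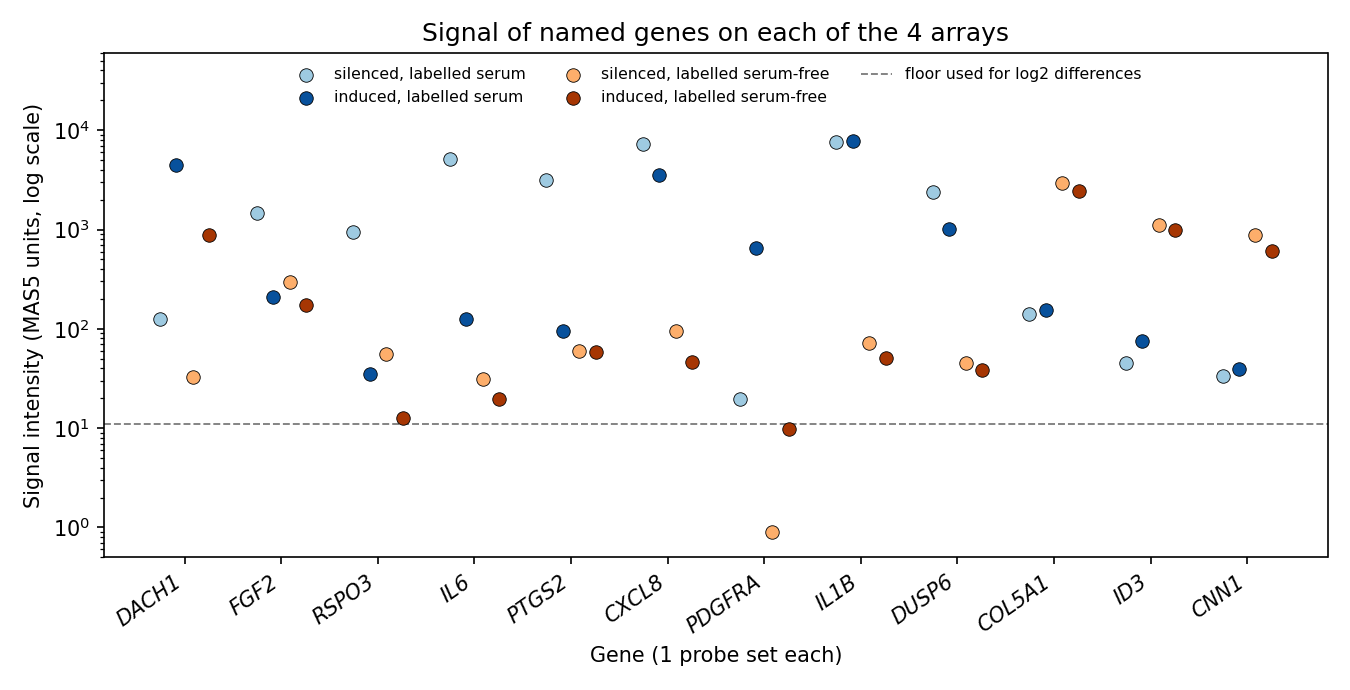
Signal intensity (MAS5 units, log scale) of 12 named genes, 1 probe set each, on the 4 arrays; each dot is 1 array and the dashed line is the floor of 10.9. DACH1 was higher in both induced cultures (4431 and 875.1), IL6 and PTGS2 were high only in the silenced array labelled serum among the 4 arrays, and IL1B and DUSP6 were high in both arrays labelled serum.

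The same comparison was made in the arrays labelled serum-free, where the differences were smaller. RSPO3 was again lower with DACH1 induced, 4.39-fold (55.7 and 12.7), as were the collagen gene COL8A1, 2.45-fold (1242 and 506.3), and CXCL8, the interleukin 8 gene, 2.04-fold (95.2 and 46.6). FGF2 was 1.73-fold lower (299.6 and 172.7), with 1.76-fold for its other probe set. TGM2, which encodes transglutaminase 2, was 2.22-fold higher (34.8 and 77.2). IL6 was already low, at 31.6 and 19.6, and PTGS2 was at 59.8 and 57.8.

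Of 12659 genes in this pair, 129 were at least 2-fold higher and 344 lower, 3.7% of the genes. The share lower was 72.7%, and with quantile normalization of the 4 arrays 153 were higher and 210 lower, a share of 57.9%. Most of the count came from dim genes: 419 of the 473 had no array at or above a signal of 50, and only 2 of 3869 genes with a brighter signal from 200 to 1000 passed 2-fold, against 225 of 3960 in the arrays labelled serum. After DACH1, the genes highest by measured difference were SMPD2 (13.7 and 50.2), SPDEF (13.3 and 45.0), CHRNB2 (15.4 and 48.4) and IL37 (13.0 and 37.8), all near the floor. EGF itself, whose product the serum-free medium contains, read 64.6 and 18.9, and MAP2 read 85.1 and 25.9. SLC11A1, at least 5.23-fold lower, and TMEM184A, at least 5.43-fold lower, were bounds.

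List medians were small in this pair. The one furthest from 0 was -0.54, for 4 markers of other cell types, inside the range of random lists (-0.60 to 0.41). The NF-kB and cytokine list had 1 of 16 members at least 2-fold lower and a median of -0.13, which turned to 0.31 with a floor of 50 and only genes with an array at 100 or more, and the ATF4 list had a median of -0.14. ER chaperones had a median of -0.14, S phase genes 0.18 and G2 and M phase genes -0.17. Cholesterol biosynthesis (-0.14) and the TGF-beta and BMP response (-0.15) lay below 0 here and above 0 in the arrays labelled serum. Housekeeping genes had a median of -0.17, of about the same size as these shifts. Genes tied to DACH1 in earlier work had a median of -0.43, with 7 of 9 members below 0. These genes, neural stem markers (-0.36), astrocyte markers (-0.32, SLC1A3 1.52-fold lower) and matrix genes (-0.15) lay under the range of their random lists. So did housekeeping genes (range -0.125 to 0.082), fatty acid synthesis (-0.18) and the serum response list (-0.13). The NF-kB, ATF4, ER chaperone, cholesterol, TGF-beta and G2 and M phase lists did too, while S phase genes lay above theirs. Lying under random lists thus did not set a list apart from housekeeping genes in this pair. The FGF and ERK list had a median of 0.03 and a mean of -0.04, and the respiratory chain -0.01 and 0.02. With quantile normalization the medians of the respiratory chain, the p53 response (0.01) and the interferon response (-0.08) changed sign.

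Across both media, 40 genes were at least 2-fold different in the same direction, of 11475 compared in both. DACH1 stood first among the 10 that were higher, followed by DECR2 (2.71-fold labelled serum, 2.77-fold labelled serum-free). TGM2 was the only gene of the 10 besides DACH1 with a signal above 100 on any array. Of the 30 that were lower, RSPO3 led, then MAP2, ZNF414, CEACAM5, MAP3K7CL and COL8A1. RSPO3 and COL8A1 reached signals of 945 and 1242, with COL8A1 3.85-fold and 2.45-fold lower, and the other 4 mostly read under 50. Independent lists of these sizes would share 2.22 higher and 7.90 lower genes. Genes that went in opposite directions exceeded their expectation too, with 16 against 8.52. The excess was thus not confined to genes that agreed. With quantile normalization 14 were higher and 20 lower in both, so the balance of directions depends on scaling. These pairs have no array in common, and the correlation of their differences across genes, which are not independent replicates, was 0.105. With every array required above the median signal, the count of 40 became 8.

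In the limma fit of DACH1 state with medium as a second term, 0 of 12103 genes passed an adjusted p of 0.05, and 585 had an unadjusted p under 0.05. Adjusted over each list alone, 1 neuronal marker passed as higher (GAP43) and 1 as lower (MAP2), and 0 genes of the other lists. GAP43 read 0.7 on the silenced and MAP2 4.4 on the induced array labelled serum, so both differences and their errors depend on the floor. DACH1 had the smallest adjusted p, 0.234, at a log2 difference of 4.94 (SE 0.20, higher in 2 of 2 induced arrays). With a trend in the variance prior, DACH1 alone passed at an adjusted p of 0.0104 in limma. The fit has 1 residual degree of freedom per gene, and in simulated data it found 0 of 55 genes changed 2-fold, 51 of 75 changed 4-fold and 64 of 70 changed 8-fold.

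**Figure D2:**
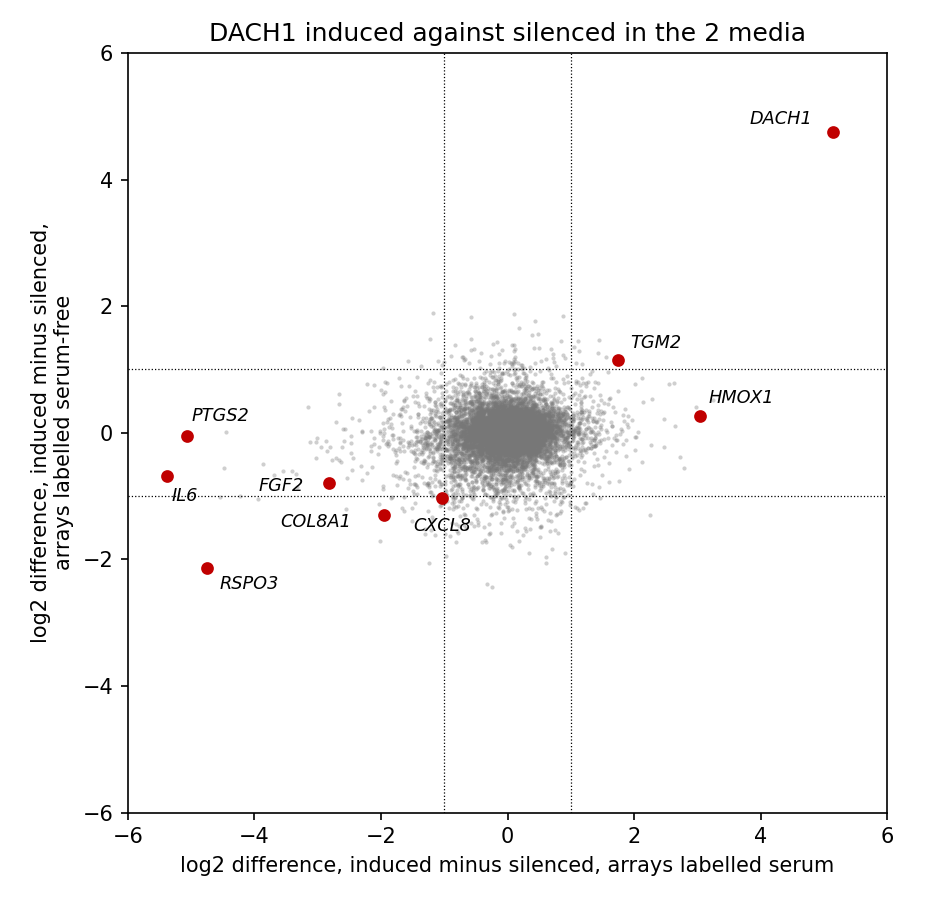
Each point is 1 of 11475 genes, placed by its log2 difference of induced minus silenced signal in the arrays labelled serum (horizontal) and labelled serum-free (vertical); dotted lines mark 2-fold. DACH1 lies at 5.14 and 4.75, RSPO3 at -4.75 and -2.13, and IL6 and PTGS2 lie far to the left and near 0 vertically.

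How far the DACH1 difference itself depended on the medium can be given only as values, since no array is left to estimate an error. For 653 of 12103 genes the log2 difference was at least 1 higher in the arrays labelled serum-free, and for 576 at least 1 lower. Among these genes, which are those of the limma fit, PTGS2, IL6, GALNT5, FGF7 and ITGB8 had the highest differences of differences. FGF7, a fibroblast growth factor gene, read 280.4 and 18.0 labelled serum and was under the floor on both arrays labelled serum-free. The lowest among them were PDGFRA, DHRS9, TRIML2, TGFA and GPR153. PDGFRA was under the floor on both arrays labelled serum-free, and DHRS9 and GPR153 on some arrays, so their places depend on the floor. TGFA, which encodes a ligand of the EGF receptor, was 6.63-fold higher with DACH1 in the arrays labelled serum and 1.31-fold lower in those labelled serum-free.

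The second question was how the culture medium changed expression. Many NF-kB and cytokine genes and the collagenase gene MMP1 were lower in the arrays labelled serum-free than in those labelled serum, and many genes of matrix and cell division were higher. IL1B, the interleukin 1 beta gene, fell 126-fold (log2 difference -6.97, SE 0.22, limma adjusted p 0.0157), and CXCL8 fell 76.2-fold (-6.25, SE 0.18, adjusted p 0.0157). MMP1 fell 63.9-fold (SE of the log2 difference 0.18, adjusted p 0.0157). COL5A1, a fibrillar collagen gene, rose 18.1-fold (4.18, SE 0.20, adjusted p 0.0167), and CNN1, a smooth muscle calponin gene, rose 20.1-fold (4.33, SE 0.26, adjusted p 0.0167). Each of these was named for a large difference in both the silenced and the induced pair, so that agreement is no further check.

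The limma fit called 1862 genes higher and 1534 lower of 12103 in the arrays labelled serum-free. Counted at 2-fold without a test, 1972 were higher and 1580 lower of 12906 in silenced cells, and 1732 and 1255 of 12371 in induced cells. Of genes compared in both states, 1121 were higher in both pairs and 831 lower, against 257 and 153 expected of independent lists, and the differences correlated across genes at 0.812. The spread in this fit is the DACH1-by-medium difference in single arrays, so its p-values do not measure the spread between cultures. With no filter on low signals the fit called 0 genes at an adjusted p of 0.05, although 4531 had an unadjusted p under 0.05.

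Besides IL1B, CXCL8 and MMP1, the genes named as lowest in both pairs were IL24 (130-fold, adjusted p 0.0157 in limma), the interleukin 1 receptor antagonist gene IL1RN (63.6-fold), CXCL2 (98.8-fold), IL33, CCL20, CSF3 and TCIM. IL33, CCL20, CSF3 and TCIM lay under the floor on both arrays labelled serum-free, so their differences are bounds: CCL20 was at least 324-fold lower in silenced and 95.5-fold lower in induced cells. The highest were TNFRSF9, CPA4, ALPK2, COL8A1, TMEM255A, CNN1, COL5A1, WFDC21P, FLG and ID3. TMEM255A rose 20.5-fold (70.3 and 69.7 against 1445 and 1429), and COL8A1 rose 21.7-fold, both at an adjusted p of 0.0167 in limma. IGFBP3, an IGF binding protein gene, rose 16.6-fold, from 807.7 and 356.1 to 10258 and 7753.

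All 24 measured genes of G2 and M phase rose, by limma over all genes and when adjusted over the list alone. KIF20A, a mitotic kinesin gene, rose 8.38-fold, the proliferation marker MKI67 6.23-fold and BIRC5 5.37-fold. Of 21 genes of S phase, 16 rose and 0 fell, and 18 rose when adjusted over the list alone. RRM2, a ribonucleotide reductase gene, rose 5.05-fold and UHRF1 3.92-fold. Of the p53 response 9 of 16 fell, 11 when adjusted over the list alone, among them MDM2 (4.34-fold) and GADD45A (3.45-fold), and 1, TP53I3, rose. Hypoxia and glycolysis genes rose in 12 of 22 cases, 15 when adjusted over the list alone, with PFKFB4 at 10.3-fold, SLC2A1 at 5.90-fold and PDK1 at 5.76-fold.

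Matrix genes rose in 12 of 20 cases and fell in 1, or 15 and 1 when adjusted over the list alone. COL1A2, a chain of type I collagen, rose 13.0-fold and the lysyl oxidase gene LOX 9.73-fold. The serum response list was split, with 7 of 19 up and 5 down (9 and 6 adjusted over the list alone): the actin-binding genes CNN1 and TAGLN (10.2-fold) and the smooth muscle actin gene ACTA2 (7.53-fold) rose, while the immediate early genes EGR1 (28.3-fold) and FOS fell. The direction for TAGLN rests on its probe set: without _x_at and _s_at probe sets its log2 difference was -0.28 in silenced and -0.93 in induced cells. THBS1, the thrombospondin 1 gene, rose 23.2-fold. Genes of the TGF-beta and BMP response rose in 7 and fell in 4 of 18 cases (9 and 5 adjusted over the list alone). ID1 and ID3, targets of BMP signalling, rose 10.2-fold and 18.1-fold, while the ligand genes BMP2 and INHBA fell 17.2-fold and 22.7-fold.

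NF-kB and cytokine genes fell in 13 of 19 cases and rose in 0, with 15 down when adjusted over the list alone. IL6 did not pass (adjusted p 0.0506 in limma), at 5184 and 124.5 against 31.6 and 19.6. The FGF and ERK list had 11 of 21 members down and 1 up, in both adjustments. DUSP6, a feedback phosphatase induced by ERK, fell 37.4-fold, and the feedback inhibitor gene SPRY2 fell 11.9-fold. These arrays are labelled with the medium that holds basic FGF and EGF, which signal through ERK, and DUSP6 was at 45.3 and 38.1 there against 2383 and 1012 in the arrays labelled serum. The labels of the medium were kept as given, and every direction drawn between media rests on them. FGF2 had an adjusted p of 0.147 in limma for the medium, since the silenced pair differed 4.93-fold and the induced pair 1.21-fold. DACH1 fell 4.43-fold by its brightest probe set (adjusted p 0.0177 in limma). That probe set was far higher in the induced arrays, and whether it reads the construct or the cells' own gene was not analysed here.

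Of the ATF4 list 9 of 27 fell and 2 rose (10 and 2 adjusted over the list alone). CTH fell 8.63-fold and ATF3 8.79-fold, whereas STC2 rose 10.4-fold and the cystine transporter gene SLC7A11 7.45-fold. ER chaperones rose in 6 of 16 cases, 8 when adjusted over the list alone, with CRELD2 at 4.12-fold. Neuronal markers rose in 5 of 7 cases in both adjustments, among them the neuronal enolase gene ENO2 (9.28-fold) and SNAP25 (3.45-fold). MAP2, 1.93-fold higher in silenced and at least 2.38-fold higher in induced cells, was among the genes lower with DACH1. Fatty acid synthesis genes rose in 3 and fell in 1 of 9 cases in both adjustments, SCD by 3.27-fold.

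Genes tied to DACH1 in earlier work fell in 4 and rose in 1 of 11 cases (5 and 2 adjusted over the list alone), and genes of the EYA and PAX network fell in 3 and rose in 1 of 7 in both. Interferon genes rose in 3 and fell in 4 of 19 (4 and 4 over the list alone), and Wnt genes rose in 2 and fell in 1 of 9 (3 and 2). Notch genes fell in 2 of 8 and rose in 0 (3 and 1 over the list alone), and neural stem markers fell in 2 of 10 in both adjustments, OLIG2 among them (58.4 and 79.9 against 12.2 and 12.3). Astrocyte markers rose in 1 and fell in 1 of 7 (2 and 1 over the list alone). Of the respiratory chain 1 rose and 3 fell of 18, and 0 when adjusted over the list alone. For cholesterol biosynthesis 1 of 17 rose, and 0 over the list alone. The serum response median was -0.10 in silenced cells against a mean of 0.59, the TGF-beta and BMP median 0.07 in induced cells against -0.01, and the EYA and PAX median 0.07 in silenced cells against -0.38. The interferon median was -0.18 in induced cells against a mean of 0.01, and that of other cell types 0.06 over both states against -0.09. None of the 3 oligodendrocyte markers or of the 3 markers of other cell types passed. Of 11 housekeeping genes 1 rose, ACTB, by 1.84-fold (adjusted p 0.0423), and 0 over the list alone.

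**Figure D3:**
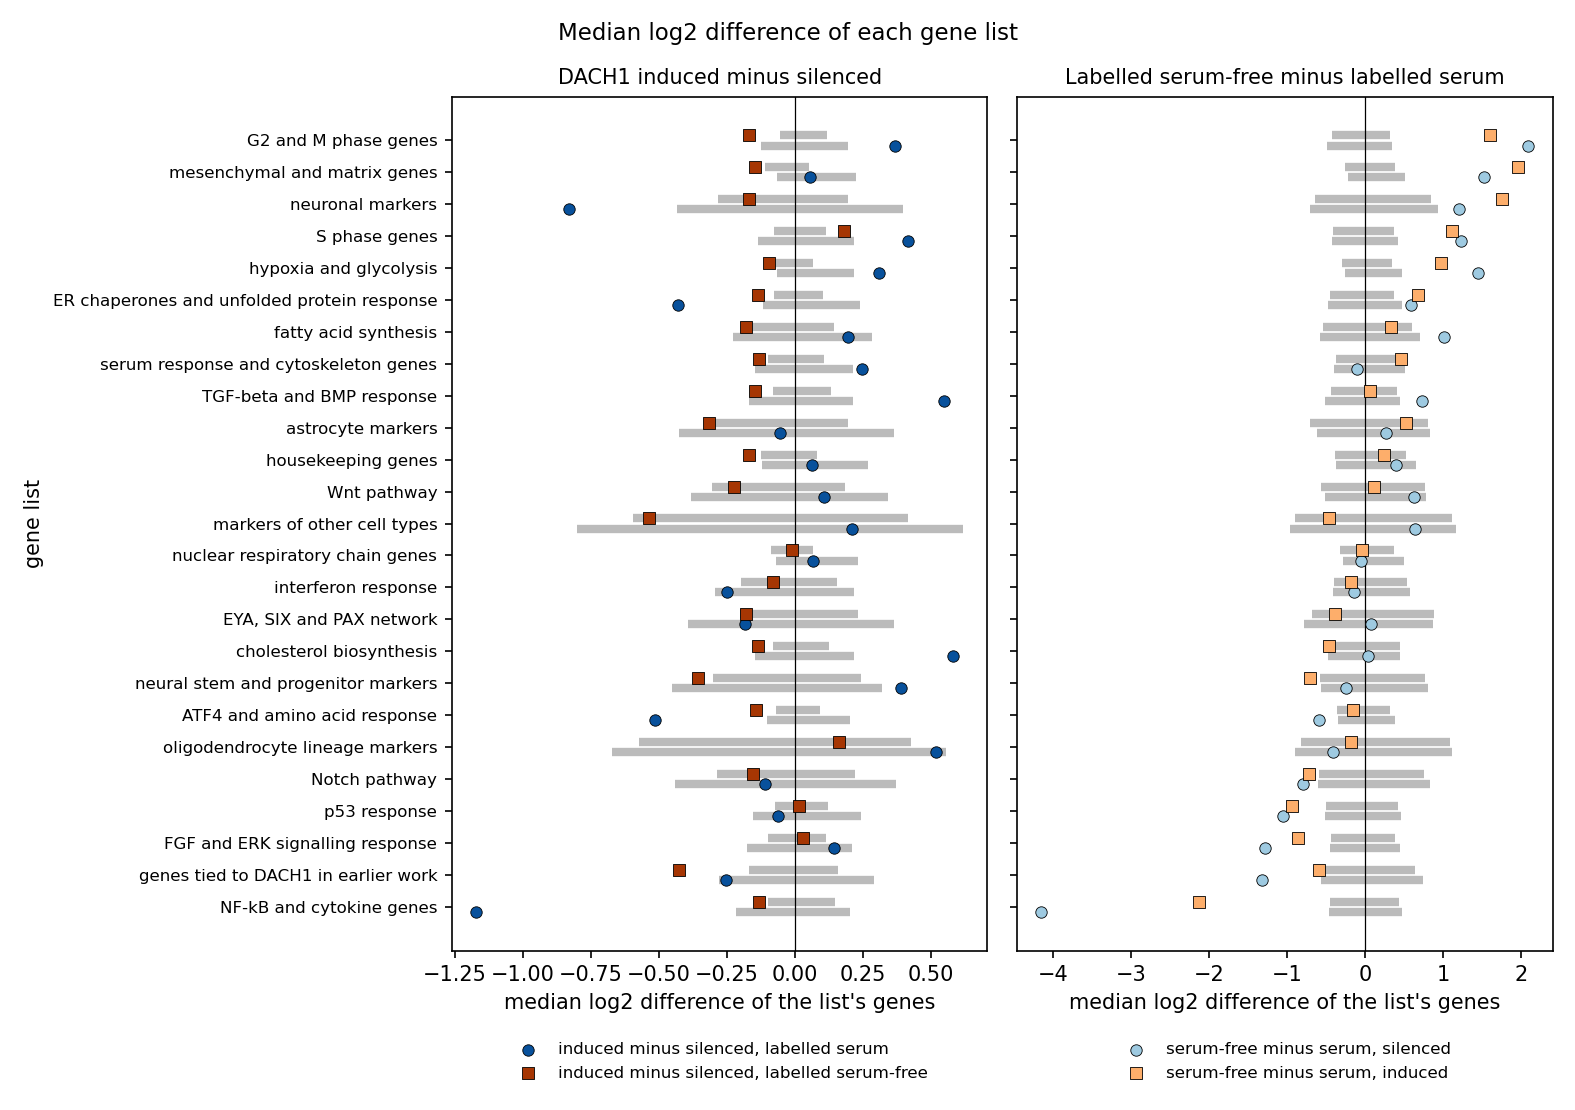
Median log2 difference of each of the 25 gene lists, for DACH1 induced minus silenced (left) and for arrays labelled serum-free minus labelled serum (right), with 1 symbol per pair of arrays and grey bars for the range of 95% of random lists matched on signal. The NF-kB and cytokine list had the lowest median of the 25 lists for DACH1 in the arrays labelled serum (-1.17), and the G2 and M phase list the highest for the medium in silenced cells (2.09).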

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

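The tests of scaling, of low signals, of cholesterol genes, of the cytokine list and of ATF4 targets were chosen only after the results were seen, while the test of glucocorticoid-induced genes was set before its genes were looked at.

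Of the genes compared in both media, 16 were at least 2-fold different with DACH1 in opposite directions, against 8.52 expected of independent lists; whether they differ between media was not tested. DHRS9 was higher with DACH1 in the arrays labelled serum and lower in those labelled serum-free, with a difference of differences of -3.55, and NEU4 went the other way, at 3.07. Both were dim, DHRS9 at no more than 51.6 and NEU4 at no more than 40.6, and each lay under the floor on 2 of the 4 arrays, so these values depend on the floor. Outside the named genes, 18 probe sets without 1 named gene were at least 2-fold different in the same direction in both media, 5 higher and 13 lower with DACH1, of 4439 compared. Independent lists would share 1.62 and 6.03, and 1 of the 18 had a signal of 100 or more on any array.

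The arrays labelled serum-free had lower FGF and ERK genes and higher matrix genes, which is opposite to what the listed growth factors and the absence of serum would lead one to look for. A difference in scaling between arrays is argued against by quantile normalization, which left the FGF and ERK median at -0.81 in the DACH1 state nearer 0. An exchange of the medium labels is a possible explanation, since it would turn both directions. B-27 contains corticosterone, and 7 measured glucocorticoid-induced genes had a median of -0.44, lower in the arrays labelled serum-free, but inside the range of random lists (-0.67 to 0.78). Cholesterol genes, which cells without lipoprotein tend to raise, had a median of -0.14, also inside it, so exchanged labels and media acting as labelled cannot be told apart from these values.

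More genes differed 2-fold with DACH1 in the arrays labelled serum than in those labelled serum-free. Noise of low signals is argued against, since with a floor of 50 and an array at 100 or more the counts were 425 and 11, a ratio of 38.6. Stress from doxycycline by way of ATF4 would raise its targets, and their median was -0.52, so no net rise was seen. A fall with DACH1 could mask such a rise, so this median does not decide that route. The labels do not say how the silenced cells were handled, and no array held cells without the DACH1 construct. If the silenced cells received no doxycycline, its effects cannot be told apart from those of DACH1 in any of these comparisons. A particular state of the single silenced culture labelled serum may still account for part of it, but the other pair cannot decide this. The NF-kB and cytokine list had a median of -0.13 there, which turned to 0.31 with that floor of 50, where IL6 and CXCL2 are too dim to be included. In silenced cells the list was already lower labelled serum-free, with a median of -4.15. CCL20, CSF3 and CXCL1 lay under the floor on both of those arrays, so a further fall with DACH1 could hardly be seen. The medium and the 5.06-fold higher DACH1 level in the array labelled serum stay open as untested explanations.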

How the results depend on the processing

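The setting with a floor of 50 and at least 1 array at 100 or more was chosen only after the results were seen. The limma fit sets induced against silenced within each medium, and no other pairing was made, since each condition has 1 array. Of 74 counts under an alternative, 48 stayed within 1.5 times and 26 did not. The 74 include each array left out, where a 2-fold count of 1 pair was set against the limma count, an unlike measure. Of the values of named genes 5778 moved by less than 1.5-fold, 587 by more in the same direction or from under 2-fold, and 15 turned. Of 400 list medians 386 moved by less than 1.5-fold, which includes small ones that crossed 0 inside the random range, 13 moved by more, and 1 that lay outside that range turned. Except where a value shows it, the cause was not tested. Low signal limits the results: in the arrays labelled serum-free, 419 of the 473 genes 2-fold different with DACH1 had no array at or above 50. In the arrays labelled serum it was 363 of 936. Among genes this dim the share past 2-fold was alike in both pairs, 12.07% labelled serum and 12.35% labelled serum-free. The share of probe sets at or under the main floor, 36.97% to 42.14% per array, follows from its definition as the 40th percentile.

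Genes 2-fold different with DACH1 in the arrays labelled serum numbered 936, but 579 with every array above the median and 425 with the added floor of 50. In the arrays labelled serum-free, 473 became 780 with no floor, 275 with a pseudocount, 87 with every array above the median, 244 with the mean of all probe sets and 11 with the added floor. The added floor gave 2280 and 1929 for the medium in silenced and induced cells. The 40 genes alike in both media became 68, 12, 8, 20 and 3 under those 5 settings in the same order. Differences of differences past 2-fold numbered 1229, and 771 with a pseudocount, 689 with every array above the median, 739 with the mean of all probe sets and 358 with the added floor. For DACH1 the limma count of 0 became 1 with every array above the median or with a trend. For the medium, 3396 became 2163 with no floor and 0 with no filter. The fit with no filter held 19775 genes, and its variance prior had 0.44 degrees of freedom against 2.93. Which of these lowered the count was not tested. Leaving out an array leaves 1 pair and no test: 473 to 936 genes were 2-fold different for DACH1, and 2987 to 3552 for the medium.

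DACH1 itself came to 1.74 and 1.53 (log2) in the 2 media with the mean of its probe sets, to 0.10 and -0.15 without _x_at and _s_at probe sets, which drops its brightest, and to 4.13 labelled serum-free with the added floor. Other values turned with the probe sets used: without those probe sets ERN2 gave 0.88 (DACH1, serum-free) and 1.23 (medium, induced), GINS2 -0.29, IDI1 1.41, SLC1A2 0.18 and TAGLN -0.28 and -0.93 in silenced and induced cells. With the mean of all probe sets ERN2 gave 0.056, IDI1 0.019 and SPDEF 0.077. SLC1A2 gave 0.10 with a pseudocount and -0.97 with no floor. With the added floor SPDEF gave -0.16 for DACH1 and 0.16 for the medium, and the NF-kB and cytokine list 0.31 for DACH1 in the arrays labelled serum-free.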

Other observations

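Gene families chosen after seeing the data, some of which share members with the fixed lists, differed between the media too. Of the histone cluster genes, 11 of 16 fell in the arrays labelled serum-free by limma and 0 rose, with a median log2 difference of -1.46 (-1.52 with quantile normalization). Which histone transcripts these probe sets read was not analysed here, so this fall does not speak to histone expression in S phase. H2AC6 fell 5.15-fold (adjusted p 0.020), H2BC5 3.85-fold and H2BC12 2.66-fold, from 1067 and 1408 to 460.5 and 461.4. Genes of the replicative helicase and the GINS complex rose in 10 of 13 cases and fell in 0. Alpha and beta tubulin genes rose in 7 of 10 cases, TUBA4A by 4.74-fold and TUBB2A by 4.15-fold. Lysyl oxidases, which crosslink collagen, rose in 4 of 5 cases, with LOXL3 at 10.8-fold and LOXL1 at 7.33-fold. These families kept their direction with quantile normalization.

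With DACH1 in the arrays labelled serum, 8 of 12 chemokine genes were at least 2-fold lower and 0 higher, with a median of -1.40 (-1.09 with quantile normalization). CXCL5 read 323.9 and 22.1. Of 14 matrix metalloproteinase genes 5 were lower and 1 higher, and MMP3, the stromelysin 1 gene, read 3064 and 824.7. Of 10 tubulin genes 4 were higher and 0 lower, TUBA1A among them (1239 and 3057). In the arrays labelled serum-free these 3 families had medians of -0.72, -0.01 and -0.17, and the metalloproteinase median was 0.03 with quantile normalization. Interleukin genes did not follow the chemokines in the pair labelled serum: of 17 measured, 2 were at least 2-fold higher and 3 lower, with a median of 0.11 (0.28 with quantile normalization). IL33 was among the higher, at 570.6 and 2740.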
